A study of Homo sapiens with 24 samples.

How the data were processed

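Expression was measured by RNA sequencing in 24 libraries of human NK cells, 6 in each of 4 groups. Per the labels' protocols, RNA was extracted with the RNeasy Micro kit and libraries were made with the SMARTer Universal Low Input RNA kit. Bowtie2, edgeR and the human build hg19 are named in the submitters' processing notes, without versions. The program that assigned reads to genes and the gene annotation are not given in the sources used here. The deposited table holds an estimated count per gene symbol and library, not scaled for depth or gene length: 41.3% of its non-zero values are not whole, at a tolerance of 0.005. Reads that fit several genes may have been shared between them by that estimate, so values of near-identical genes, such as HSPA1A and HSPA1B or HBA1 and HBA2, are uncertain. No strand setting is stated. Genes are given by symbol, without coordinates, because the annotation at hand is of another build than hg19.

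The table had 25343 rows. Before any scaling or test, 108 sex-linked genes were taken out, which left 25235, and the estimated counts were rounded to whole numbers. Every column matched 1 sample by its name. Groups came from the labels. The total count per library was 4380938 to 7430599, so 3 counts, the upper limit that a count of 0 allows, equalled 0.404 to 0.685 CPM in a single library. Counting intervals and these limits cover counting error only, since reads carry no molecular identifiers.

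The main test was fixed before the data were examined, as were the gene lists, the marker lists, the rule for named genes and most alternatives. It was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest) with TMM scaling, the filterByExpr filter and a model of the group alone, on the libraries of the groups compared. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change was its size divided by the square root of F. There were 5 comparisons: ascites 1 against medium, ascites 2 against medium, ascites 2 against ascites 1, patient ascites NK cells against medium, and patient ascites NK cells against ascites-treated cells, where the 2 treated libraries of a donor were summed so that each person counted once. CPM were scaled within each comparison, so the medium value of a gene differs slightly between comparisons. Levels of a gene with 0 to 3 reads in a group are given as reads, with a lower bound against 3 counts over the group, or a CPM ratio with its exact 95% counting interval.

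The medium and ascites libraries with the same number come from the same healthy donor, per the labels. The deviations of same-donor libraries from their group means correlated by at least 0.13, and every library correlated best with its own donor's. The fit with the donor as a block was an alternative, fixed in advance. Patients and donors with the same number are different people, and these numbers were not used to pair.

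The 27 gene lists were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation, fry, the donor block and DESeq2's size factors were alternatives. With an estimated correlation, calls held for 5 lists in ascites 2 against medium and for 0 lists in the other comparisons, and with the donor block added they held for 0 lists. The 11 marker lists of other cell types were summed in CPM per library, and log2(CPM + 1) was compared by a 2-sided exact permutation test over 64 sign changes for same-donor groups or 924 assignments for unrelated groups. The smallest p these can give are 0.0312 and 0.00216. Values were adjusted over the 11 lists of a comparison, so 64 sign changes could reach an adjusted p under 0.05 only if at least 7 lists were at the smallest p.

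The rule named, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 10 CPM that moved the same way in every donor or did not overlap between unrelated groups. It also named up to 4 called members of each list with the largest change and a mean of at least 1 CPM, or the member with the smallest p where none was called, and MUC16. HLA and KIR genes, receptor segments, small RNAs, pseudogenes and some other classes were not named. Which of the genes named by the rule are described in the text was chosen after their values were seen. Some named genes are not reported here.

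The edgeR fit and camera were tried on simulated data, drawn from the means, dispersions and library sizes of the real libraries. Known changes were put in 200 genes with a control mean of at least 5 CPM, and no donor effect was simulated. The shares below thus do not cover genes of lower level. Of genes changed 4-fold, 92% were recovered for ascites 1 against medium, 100% for ascites 2 against medium, 86% for ascites 2 against ascites 1, 96% for patients against medium and 92% for patients against ascites-treated cells. At 2-fold the shares were 50%, 68%, 34%, 18% and 24%. At most 0.04% of unchanged genes were called in any of the 5 comparisons without a block.

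Alternatives were DESeq2's size factors, no filter, a stricter filter of 1 CPM in 6 libraries, the Wald test of DESeq2 1.42.0, limma-voom, robust estimation, all 24 libraries in a single fit, the donor block, and leaving out each donor or library. Leaving out donors 5 and 6, ascites 1 donor 6, or patients 1 and 4, and split controls for the overlap of calls, were chosen after seeing the data. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.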

Results

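RNA was sequenced from human natural killer (NK) cells, lymphocytes that kill infected and tumour cells. The 24 libraries fell into 4 groups of 6. NK cells from the blood of 6 healthy donors were held for 24 h in medium, and NK cells of the same 6 donors were held for 24 h with ovarian cancer ascites, the fluid that gathers in the abdomen in this disease. The ascites came from 2 ascites donors, named ascites 1 and ascites 2 here, and every donor's NK cells met both. The last group held NK cells purified from the ascites of 6 patients, which the labels list as untreated. The total count per library was 5177128 to 6843247 in the medium group, 4380938 to 7430599 with ascites 1, 5572808 to 6565997 with ascites 2 and 4904035 to 6053769 in the patient group. The 10 most abundant genes took 8.5% to 10.1% of the counts in medium libraries and 5.2% to 17.2% in patient libraries. Levels are given as CPM, counts scaled to a common library size, as mean ± SD over 6 libraries, and log2 fold changes with their standard error (SE).

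The first comparison asked what ascites 1 did to healthy NK cells. After culture with ascites 1, some immediate early genes, which are switched on within minutes of cell stimulation, were far lower than in medium. FOS was 3872 ± 1819 CPM in medium and 11.8 ± 11.7 CPM with ascites 1, a log2 fold change of -8.35 ± 0.73. DUSP1, a phosphatase that turns off MAP kinases, was 33.5-fold lower, and JUNB was 8.36-fold lower. Some integrins and chemokine receptors found on tissue-resident lymphocytes rose: ITGA1 went from 0.66 ± 0.386 to 52.3 ± 36.7 CPM, ITGAE rose 8.53-fold, CXCR6 22.2-fold and CXCR3 18.5-fold. EOMES, a transcription factor of NK cell identity, rose from 207 ± 33.8 to 1166 ± 303 CPM, and the death ligand FASLG rose 8.69-fold. All of these genes moved the same way in 6 of 6 donors, with adjusted p-values of at most 3.77e-05.

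Killing and activation genes changed in both directions with ascites 1. Of 20 cytotoxic effectors, 2 rose and 9 fell, 2 and 10 adjusted over the list alone. GZMB fell from 2486 ± 638 to 619 ± 210.0 CPM and GZMM fell 3.8-fold. GZMH fell 5.09-fold (adjusted p = 0.00517), a call that was lost when donors 5 and 6 were left out (adjusted p = 0.0606). The list as a whole was lower (adjusted p = 0.00215 with the preset correlation, adjusted p = 0.222 with an estimated correlation). Of 25 activating receptors and adaptors, 6 rose and 6 fell over all genes, 6 and 7 adjusted over the list alone, and the list had no overall direction (adjusted p = 0.584). NCR3, which encodes the activating receptor NKp30, fell 11.2-fold, while the activation-induced receptors TNFRSF9 and CRTAM rose 8.87-fold and 7.97-fold, and 5.01-fold and 5.1-fold without donor 4. Of 18 cytokines and chemokines, 7 rose and 3 fell, 8 and 4 adjusted over the list alone, and the list test gave an adjusted p of 0.356. IFNG, the main NK cell cytokine, fell from 46.6 ± 32.6 to 5.04 ± 1.99 CPM, and AREG, a growth factor, fell 79.6-fold (52.9-fold without donor 4). Markers of the CD56dim NK subset, the more cytotoxic blood subset, fell in 13 of 17 cases and rose in 0, with 14 and 0 adjusted over the list alone (adjusted p = 2.61e-08, and adjusted p = 0.152 with an estimated correlation). The CD56dim marker SPON2 fell 16.4-fold. CD56bright markers were split, with 7 higher and 2 lower of 18, 9 and 3 adjusted over the list alone (adjusted p = 0.282): CXCR3 was among the higher and NCAM1, which encodes CD56 itself, fell 6.25-fold.

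With ascites 1, genes of the cAMP and adenosine response fell in 13 of 18 cases and rose in 0, also when adjusted over the list alone (adjusted p = 1.08e-05, and adjusted p = 0.147 with an estimated correlation). Their leading members, FOSB and AREG, are also immediate early or stimulation-dependent genes. Glucocorticoid-response genes fell in 8 of 18 cases and rose in 2, unchanged when adjusted over the list alone (adjusted p = 0.0111, and adjusted p = 0.147 with an estimated correlation); TSC22D3 fell 4.74-fold. Of 32 immediate early, AP-1 and NF-kB genes, 13 fell and 9 rose, also when adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.188). FOS and FOSB were among those lower, and EGR2 rose from 1.83 ± 1.82 to 186 ± 189.5 CPM. Of 20 TGF-beta response genes, 9 rose and 3 fell, also when adjusted over the list alone, with no call for the list (adjusted p = 0.218). Negative regulators of TGF-beta signalling were among the higher ones: PMEPA1 had 3 reads in all medium libraries and 4994 with ascites 1, a ratio of CPM of 1424 (95% counting interval 487 to 6905), LDLRAD4 rose 13.6-fold and SKIL rose 7-fold (log2 2.81 ± 0.23). Interferon-stimulated genes rose in 7 of 33 cases and fell in 1, also when adjusted over the list alone (adjusted p = 0.0306, and adjusted p = 0.656 with an estimated correlation). OASL rose 12.3-fold and IFIT1 3.01-fold. Ribosomal protein genes fell in 19 of 34 cases, 24 adjusted over the list alone, and rose in 0 (adjusted p = 2.61e-08, and adjusted p = 0.516 with an estimated correlation), with a median log2 fold change of -0.48. Fatty acid oxidation genes and PPAR targets rose in 7 of 16 cases and fell in 0, 8 and 0 adjusted over the list alone (adjusted p = 0.0445, and adjusted p = 0.511 with an estimated correlation). Of the lists for tissue residency and for homing receptors neither had an overall direction: 6 of 19 residency genes rose and 8 fell, 9 and 10 adjusted over the list alone (adjusted p = 0.64), and 9 of 23 homing genes rose and 8 fell, 9 and 10 adjusted over the list alone (adjusted p = 0.515). Cholesterol genes fell in 6 of 24 cases and rose in 2, 7 and 2 adjusted over the list alone (adjusted p = 0.0452, and adjusted p = 0.511 with an estimated correlation). Unfolded protein and integrated stress response genes fell in 7 of 23 and rose in 2, 9 and 3 adjusted over the list alone (adjusted p = 0.0221, and adjusted p = 0.222 with an estimated correlation). KLF2, which keeps lymphocytes circulating, fell 4.97-fold. Of 19 inhibitory receptors, 5 rose and 3 fell, 6 and 4 adjusted over the list alone (adjusted p = 0.632), and the checkpoint receptor TIGIT rose 3.31-fold.

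Among the largest rises with ascites 1, PLAU, which encodes urokinase, had 1 read over all medium libraries and 8275 with ascites 1, a CPM ratio of 7076 (95% counting interval 1270 to 279532). The chemokine CCL2 had 2 reads and 9833, a ratio of 4204 (1164 to 34721). CTSL, SERPINB2, MMP9 and IL1RN rose in 6 of 6 donors to means of 231 ± 306, 58.4 ± 74.4, 74.5 ± 104 and 30.0 ± 40.7 CPM, with SDs above the means. Summed monocyte or macrophage markers were lower in 6 of 6 donors in the same libraries, at 334 ± 233 CPM in medium and 225 ± 233 CPM with ascites 1 (exact sign-change permutation p = 0.0312, the smallest possible, adjusted p = 0.0688). Platelet markers were also lower in 6 of 6 donors, at 519.6 ± 884 CPM in medium and 13.9 ± 13.8 CPM with ascites 1 (exact permutation p = 0.0312, adjusted p = 0.0688). The platelet genes ITGB3, F13A1 and TUBB1 fell 122-fold, 236-fold and 81.1-fold. Their medium levels spread widely, at 4.81 to 586 CPM for ITGB3, 10.2 to 754 CPM for F13A1 and 19.6 to 1179 CPM for TUBB1, and without donor 5 F13A1 fell 71.8-fold and TUBB1 25.6-fold. T cell marker sums were 514 ± 303 and 510.3 ± 306 CPM (exact permutation p = 0.688). In all, edgeR's quasi-likelihood test called 3430 of 12424 genes, 1958 higher and 1472 lower with ascites 1. Leaving out 1 donor moved edgeR's fold change from 388 to 3229 for SERPINB2 and 4223 to 12678 for PLAU (donor 1), 1076 to 5658 for PMEPA1 (donor 2), 101 to 51.8 for EGR2 (donor 4), 160 to 79.8 for MMP9 (donor 5), and 2776 to 1530 for CCL2 and 123 to 68.9 for IL1RN (donor 6), and the fall of FOS from 327-fold to 518-fold (donor 5), all still called. For SERPINB2, PLAU and PMEPA1 the donor left out held the only medium reads of the gene. Their larger folds thus rest on a control without reads. Since all 6 libraries met fluid from 1 ascites donor, n covers the NK cell donors and not ascites.

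**Figure D1:**
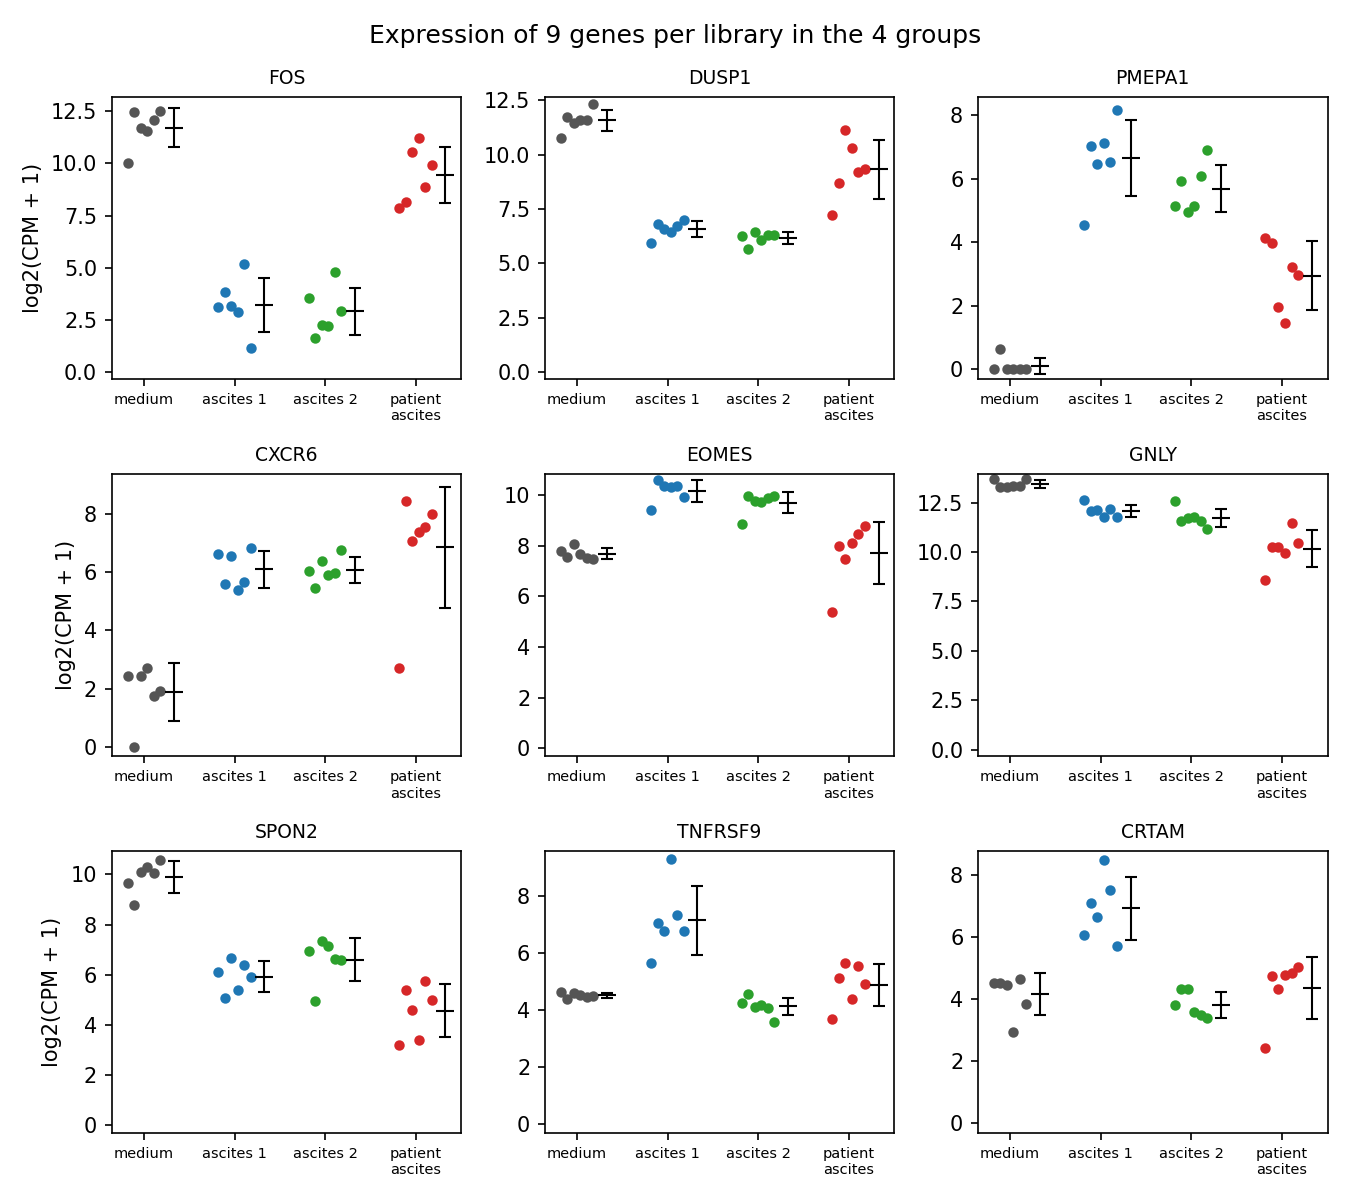
Level of 9 genes in each library on a log2(CPM + 1) axis, by group. Points are the 6 libraries of a group and the bar beside them is the mean ± SD of the plotted values. FOS and DUSP1 lie far lower in both ascites groups than in medium, PMEPA1, CXCR6 and EOMES lie higher, and TNFRSF9 and CRTAM lie higher with ascites 1 than with ascites 2.

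Ascites 2 was compared with medium in the same way. FOS was 3955 ± 1859 CPM in medium and 9.33 ± 9.8 CPM with ascites 2, JUNB fell from 966 ± 118 to 71.6 ± 12.5 CPM, and NR4A2, an orphan nuclear receptor of the immediate early class, fell 53.8-fold. IFNG fell from 47.5 ± 33.1 to 1.58 ± 1.04 CPM. CXCR6 rose 21.3-fold, CXCR3 10.9-fold, ITGA1 28-fold, ITGAE 6.26-fold and EOMES 4.1-fold, and FASLG rose from 30.4 ± 9.7 to 270.4 ± 56.8 CPM. PLAU and PMEPA1 rose from 1 and 3 reads in all medium libraries to 2911 and 2251 reads with ascites 2. The CPM ratios were 2306 (95% counting interval 414 to 91127) for PLAU and 594 (203 to 2885) for PMEPA1. EPHA1, a receptor tyrosine kinase, rose from 0.624 ± 0.603 to 106 ± 60.4 CPM. All of these moved the same way in 6 of 6 donors, with adjusted p-values of at most 0.00011.

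Among 31 immediate early, AP-1 and NF-kB genes, 16 fell and 2 rose with ascites 2, also when adjusted over the list alone. The list was lower (adjusted p = 1.63e-06), and remained past the threshold with an estimated correlation (adjusted p = 0.0282), but not when the donor was also a block (adjusted p = 0.174). The 4 lists that follow had the same adjusted p with an estimated correlation, and were also lost with the block added, at 0.174 for the IL-2, cAMP and cholesterol lists and 0.199 for the glucocorticoid list. Genes of the IL-2, IL-15 and STAT5 response fell in 13 of 21 cases and rose in 2, 14 and 3 adjusted over the list alone (adjusted p = 1.83e-05); OSM fell 21.7-fold and SOCS3 9.17-fold, while CISH, a feedback inhibitor of cytokine signalling, rose 6.38-fold. The cAMP and adenosine list fell in 13 of 17 cases and rose in 2 (adjusted p = 8.27e-06), and the glucocorticoid list fell in 10 of 18 cases and rose in 2 (adjusted p = 0.000606). Both counts were the same adjusted over the list alone. Cholesterol synthesis and uptake genes fell in 12 of 24 cases and rose in 1, also when adjusted over the list alone (adjusted p = 0.00175).

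A further 7 lists were lower with ascites 2 and lost their call with an estimated correlation. Ribosomal protein genes fell in 31 of 34 cases, 33 adjusted over the list alone (adjusted p = 5.54e-13, and adjusted p = 0.336 with an estimated correlation); RPS2 fell 2.34-fold. Cytotoxic effectors fell in 10 of 20 cases and rose in 3, also when adjusted over the list alone (adjusted p = 0.0031, and adjusted p = 0.336 with an estimated correlation). GNLY, a pore-forming granule protein, fell from 11487 ± 1673 to 3581 ± 1242 CPM and CTSW fell 4.92-fold. Activating receptors fell in 11 of 25 cases and rose in 5, 12 and 5 adjusted over the list alone (adjusted p = 0.0074, and adjusted p = 0.336 with an estimated correlation). NCR3 fell 10.1-fold and CD160 7.5-fold. Glycolysis genes fell in 10 of 21 cases and rose in 2, 12 and 2 adjusted over the list alone (adjusted p = 0.0023, and adjusted p = 0.336 with an estimated correlation); GAPDH fell 1.99-fold. CD56dim markers fell in 12 of 17 cases, also when adjusted over the list alone (adjusted p = 9.34e-06, and adjusted p = 0.218 with an estimated correlation). Oxidative phosphorylation genes fell in 18 of 32 cases and rose in 2, 20 and 3 adjusted over the list alone (adjusted p = 0.000235, and adjusted p = 0.38 with an estimated correlation). Unfolded protein and integrated stress response genes fell in 5 of 23 cases and rose in 2, 5 and 1 adjusted over the list alone (adjusted p = 0.0207, and adjusted p = 0.393 with an estimated correlation). PPAR targets rose in 5 of 16 cases and fell in 0, 7 and 1 adjusted over the list alone, and passed with the donor as a block (adjusted p = 0.0313, and adjusted p = 0.373 with the block and an estimated correlation) but not without it (adjusted p = 0.122). In these libraries platelet markers fell to 13.2 ± 19.2 CPM from 533 ± 907 CPM in medium, and monocyte or macrophage markers were 155 ± 232 CPM against 341 ± 239 CPM. Erythroid markers were 258 ± 273 CPM in medium and 13.1 ± 10.9 CPM with ascites 2, plasma cell markers 220 ± 215 and 51.2 ± 45.6 CPM, and T cell markers 525 ± 308 and 412 ± 283 CPM. All 5 sums were lower in 6 of 6 donors (exact permutation p = 0.0312, adjusted p = 0.0573). In all, edgeR called 4657 of 12575 genes, 2410 higher and 2247 lower with ascites 2. A fit of all 24 libraries at once called 2661. Leaving out 1 donor moved edgeR's fold change from 1385 to 4191 for PLAU (donor 1) and 491 to 2638 for PMEPA1 (donor 2), and the fall of FOS from 427-fold to 703-fold (donor 5), all still called. For PLAU and PMEPA1 the larger folds rest on a control without reads, as the donor left out held the only medium reads.

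The direct comparison of the ascites samples asked where their effects differed. The activation receptors TNFRSF9 and CRTAM were lower with ascites 2 in 6 of 6 donors. TNFRSF9 was 213 ± 231 CPM with ascites 1 and 18.2 ± 3.88 CPM with ascites 2 (log2 fold change -3.54 ± 0.52, adjusted p = 0.0433), and CRTAM was 160.1 ± 122 and 14.9 ± 4.68 CPM (-3.42 ± 0.44, adjusted p = 0.018). Without donor 4 the TNFRSF9 log2 fold change was -2.72 (adjusted p = 0.0108). T cell markers, 554 ± 333 and 439 ± 301 CPM, were also lower with ascites 2 in 6 of 6 donors (exact permutation p = 0.0312, adjusted p = 0.344). SLA, an adaptor that dampens receptor signalling, was the only other call, at 1382 ± 424 and 511 ± 81.4 CPM (-1.43 ± 0.22, adjusted p = 0.0433, lower in 5 of 6 donors), and is named after its values were seen. Thus 3 of 12618 genes were called, all lower with ascites 2, and 1116 had an unadjusted p under 0.05. With the donor as a block edgeR called 69 genes, 9 higher and 60 lower, among them EGR2 (adjusted p = 0.0114), NFKBIA (adjusted p = 0.00579) and NR4A2 (adjusted p = 0.0351). Without the block these 3 had adjusted p-values of 0.0502, 0.0502 and 0.065. The 3 calls were lost in limma-voom, which called 0 genes, and DESeq2 called 113. They were also lost without donor 2, where 1 other gene was called, and without donor 3 or donor 5, where 0 were. All 3 were lost without donors 5 and 6, an alternative added after seeing the data (adjusted p = 0.677 for TNFRSF9, 0.154 for CRTAM and 0.709 for SLA). TNFRSF9 was lost without donor 6 (adjusted p = 0.178), and SLA without donor 4 or donor 6 (adjusted p = 0.288 and 0.178), in the fit of all 24 libraries (adjusted p = 0.268) and, added later, without the ascites 1 library of donor 6 (adjusted p = 0.0539). Where calls were lost, the log2 fold changes were -3.06 to -3.73 for TNFRSF9, -3.16 to -3.64 for CRTAM and -1.30 to -1.45 for SLA. Without donor 1, 41 genes were called.

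Of 28 immediate early, AP-1 and NF-kB genes, 0 passed over all genes, while 18 were lower and 0 higher adjusted over the list alone. The list was lower with ascites 2 (adjusted p = 3.71e-16, and adjusted p = 0.0589 with an estimated correlation), with a median log2 difference of -0.95. Cytokine and chemokine genes had 5 of 18 lower adjusted over the list alone and 0 over all genes (adjusted p = 4.09e-06, and adjusted p = 0.109 with an estimated correlation). IL-2, IL-15 and STAT5 genes had 6 of 20 lower and 1 higher adjusted over the list alone, and 1 lower over all genes (adjusted p = 0.000341, and adjusted p = 0.109 with an estimated correlation). Interferon-stimulated genes had 0 calls by either count and a list median of -0.34 (adjusted p = 4.4e-05, and adjusted p = 0.269 with an estimated correlation). In total 12 lists passed with the preset correlation, of which CD56dim markers alone were higher with ascites 2 (adjusted p = 0.00085, and adjusted p = 0.246 with an estimated correlation), and 0 passed with an estimated correlation. The block added 5 lists that were lower: cholesterol (adjusted p = 0.0345), glucocorticoid response (adjusted p = 0.0319), inhibitory receptors (adjusted p = 0.0319), oxidative stress and metallothioneins (adjusted p = 0.0135) and tissue residency (adjusted p = 0.0345). With the block and an estimated correlation none of the 5 passed, in that order at adjusted p = 0.241, 0.289, 0.207, 0.321 and 0.182.

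The log2 fold changes of both ascites samples against medium had a correlation of 0.90 across 12313 genes, which are not independent replicates. Both comparisons used the same medium libraries. Simulated groups with no effect, set against shared controls simulated from the medium libraries' means and spread, gave 0.51. The simulation left out the pairing by donor. The covariance was 0.66 against 0.04 in the simulation, a difference of 0.62, and splitting the medium libraries in 20 ways gave correlations of 0.72 to 0.81 (mean 0.76). Of 2707 genes called in both, 2706 went the same way, 1516 higher and 1190 lower. Independent lists would share 371.2 and 266.6. Split controls gave 1184 in the same direction on average, from fits with fewer medium libraries, so that count has no value for independent lists beside it. Simulated groups shared 0, but hardly any gene is called without an effect, so that 0 is no yardstick for the overlap.

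**Figure D2:**
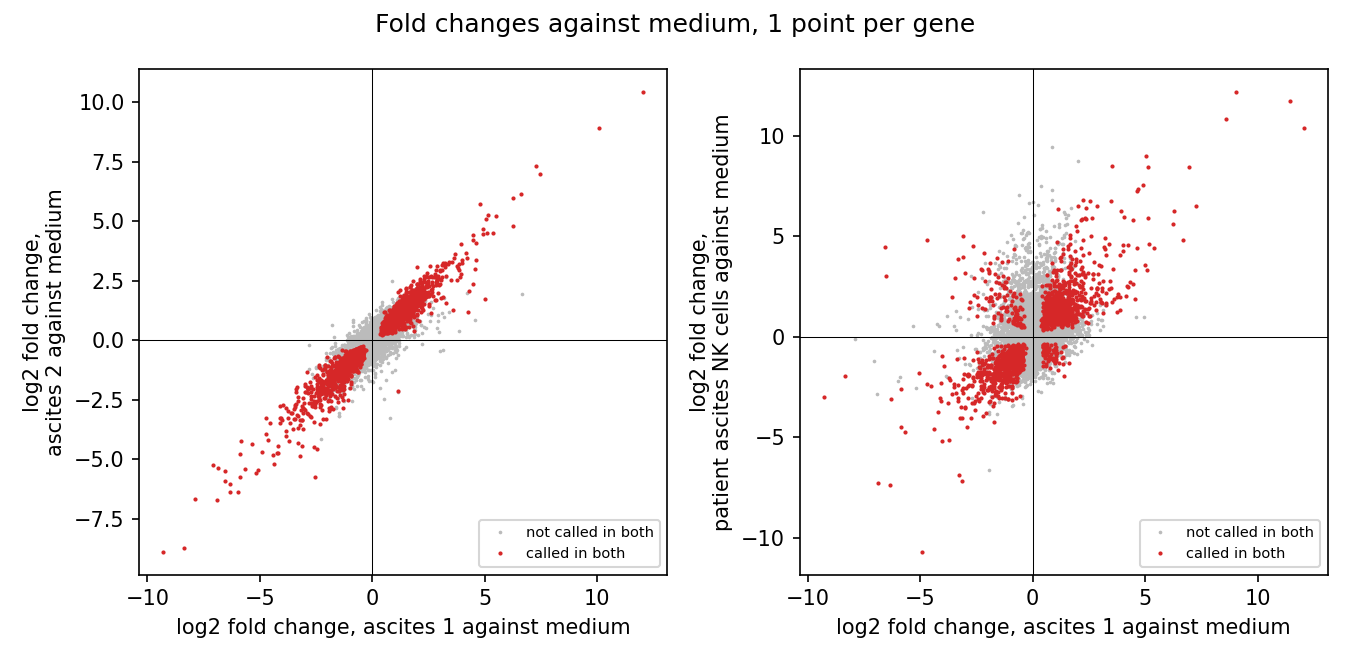
Log2 fold change of each gene with ascites 1 against medium (horizontal axis) plotted against that with ascites 2 (left) or in patient ascites NK cells (right). Red points are genes called in both comparisons and grey points are the others. The cloud on the left follows the diagonal (correlation 0.90) and the one on the right is wider (0.45).

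NK cells taken from patient ascites were compared with healthy NK cells in medium. Patient libraries held large amounts of RNA of macrophage, tumour and connective tissue genes. SPP1, a secreted protein abundant in macrophages and tumours, was 0.893 ± 0.704 CPM in medium and 17735 ± 24989 CPM in patients, and the scavenger receptor CD163 was 3.21 ± 2.25 and 1390.2 ± 1361 CPM. The macrophage gene TREM2 had 0 reads in medium and 4462 in patients, at least 1602-fold higher, and APOE had 2 and 18664 reads. The ovarian tumour and mesothelial antigen MSLN had 1 read in medium and 19001 in patients, a ratio of 20467 (95% counting interval 3673 to 808451), with adjusted p = 0.0005 in edgeR and 0.0528 in limma-voom. Its patient levels spread from 3.65 to 2875 CPM (562 ± 1141 CPM), and its log2 fold change went from 13.3 to 10.8 when the patient library that moved it most was left out. KRT19, a keratin, reached 709 ± 820.1 CPM. The collagen gene COL3A1 had 3 reads and 34924, a ratio of 12540 (4291 to 60809). The summed epithelial or tumour markers were 11.7 ± 2.22 CPM in medium and 4246 ± 5110 CPM in patients, the mesothelial or fibroblast markers 5.92 ± 2.93 and 3127 ± 3318 CPM, and the dendritic cell markers 4.02 ± 2.41 and 91 ± 55.9 CPM. Each of these sums lay above every medium library in 6 of 6 patients (exact permutation p = 0.00216, the smallest possible, adjusted p = 0.00476). Monocyte or macrophage markers were 311 ± 221 and 8528 ± 7048 CPM, above every medium library in 5 of 6 patients (exact permutation p = 0.00433, adjusted p = 0.00794). T cell markers were 477 ± 280 and 651 ± 405 CPM (exact permutation p = 0.909). Platelet and erythroid markers were lower than in every medium library in 6 of 6 patients (exact permutation p = 0.00216, adjusted p = 0.00476): PF4 had 1282 reads in medium and 0 in patients, at least 397-fold lower, and HBA2, a haemoglobin chain, was 147-fold lower.

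MUC16, the tumour antigen named in the title of the series, had 0 reads in medium, 0 with ascites 1, 1 with ascites 2 and 3595 in the patient group. A count of 0 over the medium libraries allows up to 0.095 CPM. All 6 patient libraries held MUC16 reads, at 104.8 ± 236.3 CPM with a median of 4.66 CPM, and all lay above medium (exact permutation p = 0.00216, 2-sided). The gene did not pass the filter on low counts and was not in the edgeR fit.

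**Figure D3:**
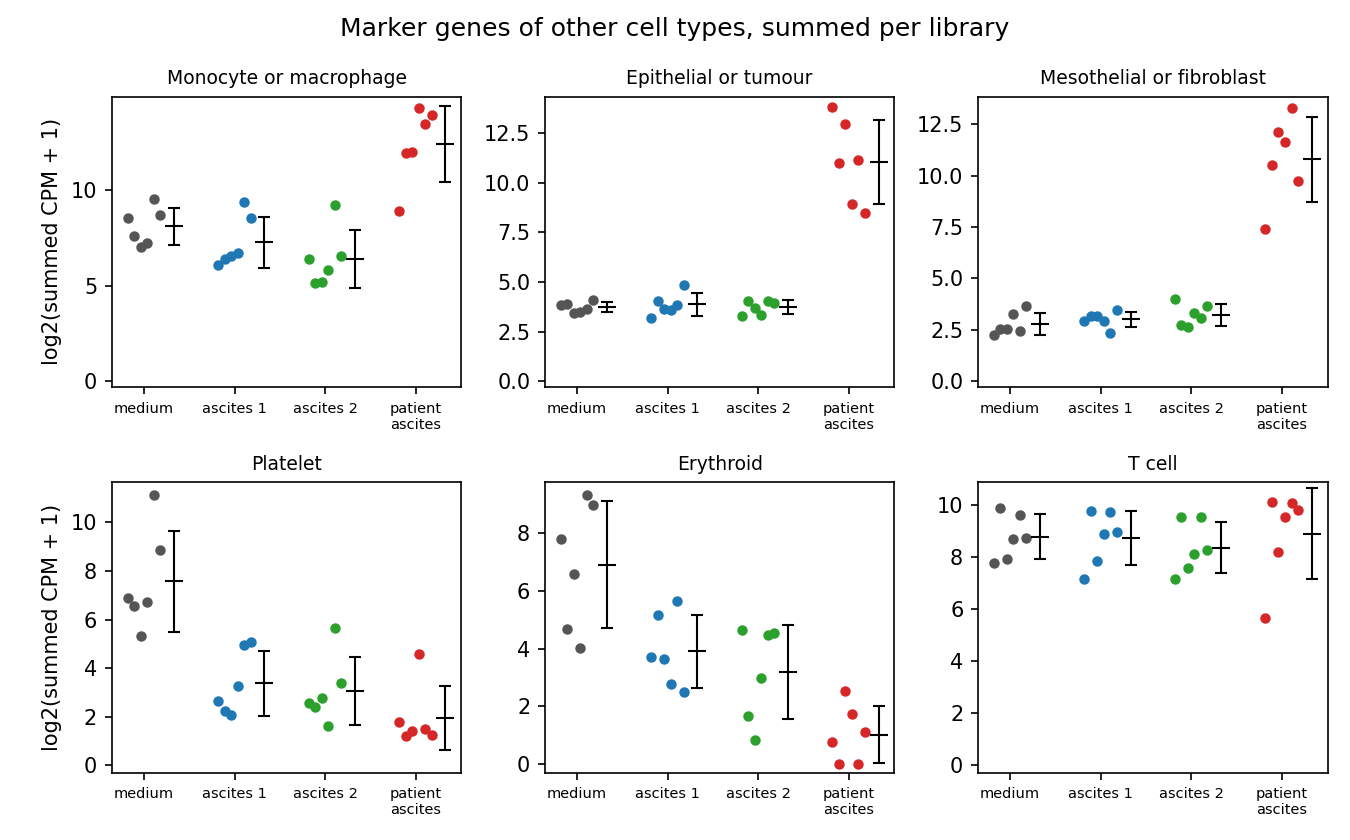
Summed CPM of marker genes of 6 other cell types in each library, on a log2(summed CPM + 1) axis, by group. Points are the 6 libraries of a group and the bar beside them is the mean ± SD of the plotted values. Epithelial or tumour and mesothelial or fibroblast sums stand far above the other groups in every patient library. Platelet and erythroid sums are highest on average in medium, where the lowest libraries overlap with the ascites-treated groups. T cell sums overlap among all groups.

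In the same libraries some genes of NK cells were lower than in medium. PRF1, which encodes perforin, fell from 6011 ± 1799 to 1075 ± 629 CPM, GZMB from 2307 ± 606 to 361 ± 214 CPM, and SPON2 37.1-fold. The transcription factors RUNX3 and TBX21, which drive NK cell maturation, fell 8.46-fold and 5.51-fold, and the receptors CD160 and NCR3 fell 11-fold and 5.71-fold. CD56dim markers fell in 14 of 17 cases and rose in 0, 14 and 1 adjusted over the list alone (adjusted p = 8.66e-06, and adjusted p = 0.71 with an estimated correlation). Activating receptors fell in 11 of 25 cases and rose in 2, also when adjusted over the list alone (adjusted p = 0.00434, and adjusted p = 0.766 with an estimated correlation). NK transcription factors fell in 8 of 27 cases and rose in 1, 7 and 1 adjusted over the list alone (adjusted p = 0.00243, and adjusted p = 0.766 with an estimated correlation). Cytotoxic effectors fell in 8 of 20 cases and rose in 3, 9 and 4 adjusted over the list alone, without a call for the list (adjusted p = 0.0591). The chemokine receptor CXCR6 rose from 3.04 ± 1.84 to 170.4 ± 109 CPM, and ITGA1 rose 48.3-fold.

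Proliferation, energy metabolism and stress genes were higher in patient libraries, alongside the macrophage and tumour markers. Cell cycle genes rose in 22 of 30 cases and fell in 1, 23 and 1 adjusted over the list alone (adjusted p = 2.32e-05), with CCNB2 43-fold and CDC20 31.6-fold higher. Heat shock genes rose in 12 of 13 cases, also when adjusted over the list alone (adjusted p = 0.000329); HSPA1B rose from 10.4 ± 4.61 to 224 ± 260.4 CPM. Glycolysis genes rose in 14 of 21 cases and fell in 0, 15 and 0 adjusted over the list alone (adjusted p = 5.69e-05), with PKM 4.22-fold and HK2 24.3-fold higher (12.1-fold without patient 3). PPAR targets rose in 13 of 17 cases, LXR targets in 8 of 13 with 2 lower, and oxidative stress and metallothionein genes in 9 of 16 (adjusted p-values 0.000329, 0.0345 and 0.0026). Adjusted over the list alone these rose in 13, 9 and 9 cases. The leading LXR target was APOE, which macrophages also make. For all 6 of these lists the adjusted p was 0.71 with an estimated correlation. Hypoxia and HIF targets rose in 12 of 20 cases and fell in 1, also when adjusted over the list alone (adjusted p = 0.009, and adjusted p = 0.766 with an estimated correlation). VEGFA, a growth factor for blood vessels, rose 47.8-fold (20.1-fold without patient 3) and ADM 122-fold. Oxidative phosphorylation genes rose in 18 of 32 cases and fell in 1, 19 and 1 adjusted over the list alone (adjusted p = 0.000612, and adjusted p = 0.766 with an estimated correlation). The cAMP and adenosine list was lower, with 8 of 18 genes lower and 1 higher, also when adjusted over the list alone (adjusted p = 0.000612, and adjusted p = 0.71 with an estimated correlation). Ribosomal protein genes were lower in 7 of 34 cases and higher in 1, 4 and 0 adjusted over the list alone (adjusted p = 0.0345, and adjusted p = 0.766 with an estimated correlation). Nuclear-retained RNAs, read as a sign of RNA quality, had 1 higher and 2 lower of 8, also when adjusted over the list alone (adjusted p = 0.322). In all, edgeR called 5562 of 12815 genes, 3304 higher and 2258 lower in patients. Leaving out 1 library moved edgeR's fold change from 10121 to 48949 for COL3A1, 19403 to 8731 for SPP1, 6468 to 3531 for TREM2, 7697 to 4542 for APOE, 4973 to 3079 for KRT19 and 21.4 to 12.6 for HSPA1B, and the falls of PF4 from 1657-fold to 689-fold and of HBA2 from 147-fold to 244-fold, all still called. For COL3A1 the library left out held the only medium reads, so its larger fold rests on a control without reads. Tissue source, person, disease and culture all differ between these groups, and other cells' markers moved with the group, so the comparison cannot assign a change to NK cells.

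The fold changes in patients against medium were set against those of the ascites treatments. The correlation across genes was 0.45 with ascites 1 and 0.34 with ascites 2, and simulated groups without an effect gave 0.51 for both. The covariances were 0.50 and 0.34 against 0.04 simulated, differences of 0.45 and 0.30. With split controls the correlations averaged 0.43 and 0.32. For the mean of both treatments the correlation was 0.39, with 0.58 simulated, a covariance difference of 0.34 and 0.37 with split controls. Of 1739 genes called with ascites 1 and in patients, 1540 went the same way (842 higher, 698 lower), where independent lists would share 423.5 and 272.6. For ascites 2 it was 1698 of 2095 (866 higher, 832 lower, against 519.3 and 416.2). With split controls the same-direction counts averaged 486 and 658. Those fits had fewer medium libraries, and the values for independent lists come from fits with all of them. The counts with split controls can therefore not be set against the values for independent lists. Simulated groups shared 0 calls, which is no yardstick here either, as they carry no effect.

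Patient NK libraries were last compared with the ascites-treated healthy NK cells, for which each donor's counts with ascites 1 and ascites 2 were summed. FOS was 10.2 ± 10.3 CPM in treated cells and 1000.2 ± 882 CPM in patients, FOSB was 70.0-fold higher and DUSP1 10.8-fold higher in patients. Some genes that had risen in treated cells were lower in patients: PMEPA1 10.5-fold, EOMES 3.83-fold, FASLG 3.54-fold and TIGIT 3.94-fold, with EOMES at 988 ± 235 CPM in treated cells and 258 ± 137 CPM in patients. Each lay outside the range of the treated cells in 6 of 6 patients, with adjusted p-values of at most 0.015. IL9R, a cytokine receptor gene, was 13.4-fold lower (23.5-fold without patient 6), and CD247, a signalling chain of NK receptors, fell from 1229.5 ± 134 to 339 ± 178 CPM. FN1, VSIG4 and MARCO, expressed by macrophages or stromal cells, reached 4445 ± 3931, 1638 ± 1877 and 802 ± 772 CPM in patients from at most 1.05 ± 1.19 CPM.

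Of the lists, 13 passed with the preset correlation and 0 with an estimated one. Heat shock genes were higher in 13 of 13 cases and glycolysis genes in 18 of 21, both also when adjusted over the list alone (adjusted p = 7.82e-05 and 1.1e-06, and adjusted p = 0.719 for both with an estimated correlation). Cell cycle genes were higher in 25 of 30 cases and lower in 2, 26 and 2 adjusted over the list alone (adjusted p = 4.21e-08, and adjusted p = 0.719 with an estimated correlation). Cholesterol genes were higher in 12 of 24 cases and lower in 1, 14 and 1 adjusted over the list alone (adjusted p = 0.00313, and adjusted p = 0.742 with an estimated correlation). Unfolded protein and integrated stress response genes were higher in 12 of 23 cases and lower in 1, 14 and 2 adjusted over the list alone (adjusted p = 0.00656, and adjusted p = 0.719 with an estimated correlation). HSPA5, an endoplasmic reticulum chaperone, rose from 465 ± 109.7 to 2222 ± 907 CPM. NK transcription factors were lower in 11 of 27 cases and higher in 2, 12 and 2 adjusted over the list alone (adjusted p = 0.00597, and adjusted p = 0.87 with an estimated correlation). Epithelial or tumour markers were 13.6 ± 5.22 CPM in treated cells and 4544 ± 5484 CPM in patients (exact permutation p = 0.00216, adjusted p = 0.00595), and monocyte or macrophage markers were 190.0 ± 225 and 9224 ± 7738 CPM (exact permutation p = 0.00433, adjusted p = 0.00952). In all, edgeR called 5645 of 13744 genes, 3202 higher and 2443 lower in patients. Leaving out 1 library moved edgeR's fold change from 97.5 to 162 for FOS, 4202 to 7465 for FN1, 4936 to 2910 for VSIG4 and 4618 to 10470 for MARCO, all still called. The comparison has the same limits of source and purity as against medium.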

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

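The test for a library that stands apart was run over 271 groups of 6 libraries: total counts, marker sums and the genes described in the text, on a log2 scale for sums and genes. Its measure is the gap between an extreme library and its nearest neighbour, divided by the range of the group. A set of 36 groups (13.3%) exceeded the critical value, where chance flags about 1 in 20 groups, or 14 here. A first count of these flags was made, then narrowed to groups of at least 1 CPM, and the full count is given here. The genes were chosen for description after their values were seen.

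In the patient group, patient 1 had the lowest value for 7 genes expressed by NK cells: PRF1 (0.679), GZMB (0.677), CXCR6 (0.763), FASLG (0.676), TIGIT (0.798), CD247 (0.76) and S1PR5 (0.694). CXCR6 ranged from 5.55 to 346 CPM in this group. The same library was lowest for FN1 (0.66) and for the sum of neutrophil markers (0.735), and patient 4 had the highest platelet marker sum (0.835). Though not flagged, the epithelial or tumour marker sum of the group was highest in patient 1, at 14320 CPM scaled over all 24 libraries. Patient 1 also had the lowest T cell, monocyte or macrophage, and mesothelial or fibroblast sums, at 49.1, 475 and 166 CPM.

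In the ascites-treated groups, donor 1 had the lowest PLAU with ascites 1 (0.828; range 3.91 to 474 CPM) and with ascites 2 (0.631; range 3.26 to 155 CPM). Donor 1 was also lowest for NR4A2 with ascites 1 (0.689) and for EOMES with ascites 2 (0.763), and highest for MSLN (1) and MARCO (0.76) with ascites 2. These highest levels were low, at 0.163 CPM for MSLN and 1.31 CPM for MARCO, where 3 counts equalled 0.498 CPM. Helper ILC marker sums were lowest in donor 4 with ascites 1 (0.723) and with ascites 2 (0.707). With ascites 2, donor 5 was highest for the monocyte or macrophage sum (0.663) and for ITGB3 (0.663), donor 6 was lowest for JUNB (0.726), donor 2 for SPON2 (0.689) and donor 3 for EGR2 (0.626). With ascites 1, donor 6 was highest for GZMM (0.798) and lowest for HSPA5 (0.779), and donor 5 was highest for MARCO (1). That MARCO level was 0.329 CPM, where 3 counts equalled 0.513 CPM.

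In medium, donor 6 had the highest total count (0.661) and the highest NCR3 (0.681). The lowest values were in donor 2 for CXCR6 (0.719), donor 1 for FOSB (0.761) and donor 4 for CD163 (0.692). For PLAU and SERPINB2 in donor 1, PMEPA1 in donor 2, MSLN in donor 5 and COL3A1 in donor 3 the value was 1, because only that medium library held any reads of the gene.

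The effects of the 2 ascites samples differed by a direct test for TNFRSF9 (adjusted p = 0.0433), CRTAM (adjusted p = 0.018) and SLA (adjusted p = 0.0433), all lower with ascites 2 in edgeR's quasi-likelihood test. These calls were lost in limma-voom and without donor 2, donor 3 or donor 5, and chance is not excluded for this comparison, since 2 of 32 splits that part every donor's pair called at least 3 genes.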

How the results depend on the processing

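The settings that left out donors 5 and 6, patients 1 and 4 or ascites 1 donor 6, and the split controls for overlaps, were chosen after seeing the data. The count for ascites 1 against medium stayed within 1.5 times of 3430 in all settings run, as did the patient counts of 5562 and 5645. Leaving out each donor or library gave 2356 to 3553 for ascites 1, 3826 to 4611 for ascites 2, 5046 to 5872 for patients against medium and 4840 to 6009 against treated cells. Without donors 5 and 6 these were 2416, 3147, 4323 and 4643, and without patients 1 and 4 the last 2 were 5497 and 5505. Without ascites 1 donor 6 the ascites 1 count was 4203. A single fit of all 24 libraries lowered the ascites 2 count to 2661, and the cause was not tested. The donor block gave 3553 and 5470 for ascites 1 and 2, and beside the calls given in the results it changed no other call of a described gene, or of a list with the preset or an estimated correlation.

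The count of 3 for ascites 2 against ascites 1 moved most: 11 without a filter, 113 with DESeq2, 0 with limma-voom, 26 with all 24 libraries, 69 with the donor block, 66 with the block and DESeq2's size factors, 1 without donors 5 and 6, and 0 to 41 when 1 donor was left out. The cause was not tested.

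Gene lists past the threshold with an estimated correlation numbered 0 for ascites 1 against medium, 5 for ascites 2 against medium (0 with the block added), and 0 for ascites 2 against ascites 1, for patients against medium and for patients against treated cells. With fry they numbered 14 for ascites 1 against medium and 3 for ascites 2 against ascites 1. Averaging log2(CPM + 1) over markers brought 7 marker lists past the threshold for ascites 2 against medium, and summing 0. With split controls the correlation of both ascites effects was 0.763, and the overlaps were 1184 for both ascites samples, 486 for ascites 1 with patients and 658 for ascites 2 with patients, from fits with fewer medium libraries.

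Uncalled lists that turned direction were heat shock in ascites 1 with the block (adjusted p = 0.844), nuclear-retained RNAs in ascites 2 with the block (0.98), homing (0.636) and inhibitory receptors (0.832) in ascites 2 with fry, and CD56bright markers in patients against medium with fry (0.971). Averaged marker lists turned, also uncalled, for epithelial markers in ascites 2 against medium (log2 0.0222), for B cell (0.177), helper ILC (0.334) and plasma cell markers (-0.0534) in ascites 2 against ascites 1, and for B cell (-0.0363) and helper ILC markers (0.331) in patients against treated cells. The cause was not tested.

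Genes described in the text gave 2423 values over 133 pairs of gene and comparison. Of these, 2382 kept their call and direction, 24 lost a call, 17 gained one and 0 changed direction. When 1 donor or library was left out, the fold change moved by over 1.5 times in 45 of the 133 pairs and by over 2 times in 24, a tally made after seeing the data. Of these 24, folds shrank for MSLN, TUBB1, F13A1, HMOX1, PF4, VEGFA, SPP1, HK2 and MMP9, and grew for SERPINB2 (8.33 times, the most), PMEPA1, COL3A1, PLAU, ITGB3, RADIL, COL1A2 and MARCO. For SERPINB2, PMEPA1, COL3A1 and PLAU the library left out held the only medium reads of the gene, which left a control without reads. Outside ascites 2 against ascites 1 the losses were MYOM2 in both ascites comparisons and MSLN in patients with limma-voom (adjusted p = 0.0517, 0.0679 and 0.0528), and GZMH with ascites 1 without donors 5 and 6 (0.0606). With total counts of 4380938 to 7430599, changes of 2-fold were often missed on simulated data.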

Other observations

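The tests of explanations and of other splits of the libraries in this part were all chosen, with their bounds, after many of the values were seen, and the lists of NK and platelet genes they use were written then too. The correlation over patients replaced an earlier count of markers called higher, which only restated the pattern.

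Markers of helper innate lymphoid cells, relatives of NK cells marked here by genes such as those of the IL-7 receptor and KIT, some of which CD56bright NK cells also express, were higher in both treated groups. Their sum was 103 ± 56.4 CPM in medium and 319 ± 135 CPM with ascites 1, and 106 ± 57.3 CPM and 316 ± 144 CPM with ascites 2 as scaled in that comparison, higher in 6 of 6 donors each time (exact permutation p = 0.0312, adjusted p = 0.0688 and 0.0573). Patients had 244 ± 144 CPM against 95.7 ± 51.4 CPM in medium (exact permutation p = 0.0411, adjusted p = 0.0646). Plasma cell markers were lower in 6 of 6 donors, at 215 ± 210 CPM in medium and 64.9 ± 63.1 CPM with ascites 1 (exact permutation p = 0.0312, adjusted p = 0.0688). RADIL, a gene linked to cell adhesion, rose 175-fold with ascites 1 and 127-fold with ascites 2 (372-fold and 307-fold without donor 6), and was 9.26-fold lower in patients than in treated cells. AREG fell 8.45-fold in patients against medium, from 128 ± 103 to 15.1 ± 12.3 CPM.

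Some NK cell genes were lower and genes of other cell types higher in patient libraries: 29 of 29 tested macrophage, tumour and fibroblast markers (38 written) were called higher, which is the pattern itself and no test of its cause. A dilution of NK RNA by a common factor would leave NK-restricted genes close to a shared fold change, but 36.4% of 33 such genes lay over 2 SE from their median log2 fold change of -1.82, from SPON2 at -5.21 to FASLG at 1.31. Of the 33, edgeR called 23 lower and 0 higher, so the calls went 1 way, and FASLG was not called (adjusted p = 0.0585). The spread argues against dilution as the whole cause of the difference from medium, although several of these genes are also expressed by T cells. Dilution as a part of the cause is not tested by this spread. Such genes also moved apart with ascites 1 in culture, where SPON2 had a log2 fold change of -4.04, EOMES 2.49 and FASLG 3.12. RNA of macrophage, tumour and fibroblast genes was present in these libraries, and whether it accounts for the lower NK genes remains open. Over the 6 patients the log2 sum of these markers and the mean log2(CPM + 1) of the NK-restricted genes had a Pearson correlation of 0.04 (exact permutation p = 0.926). The Spearman correlation was 0.20 (exact permutation p = 0.714). With 6 patients, and tumour and macrophage markers pooled in 1 sum, this cannot decide. A difference in NK cell state, by tissue, person, disease or culture, stays open and was not tested apart from these.

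CCL2, CTSL, SERPINB2, MMP9 and IL1RN, 5 genes that monocytes can express and that were grouped after their values were seen, were higher with ascites 1, while the fixed list of monocyte or macrophage markers had a lower sum in 6 of 6 donors. A larger share of monocytes would raise their abundant transcripts together, but the median log2 fold change over 12 monocyte or macrophage markers was -1.03, with 4 lower (VCAN at -6.56, LYZ at -1.32) and 2 higher (CD68 at 2.23). A change in monocytes already present could also raise such genes, and remains open: the mean log2(CPM + 1) of the 5 genes with ascites 1 and the donor's monocyte marker sum in medium, on the same scale, had a Pearson correlation of 0.60 over 6 donors (exact permutation p = 0.211) and a Spearman correlation of 0.49 (p = 0.356). Without the 2 donors whose marker sums lay farthest from the median the Pearson correlation was 0.16, so the relation rests on those donors.

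Platelet genes were lower with ascites 1 and ascites 2. Loss of platelet RNA during culture with ascites may account for it, and would lower these genes alike. With ascites 1, 61.1% of 18 platelet genes lay within 2 SE of their median log2 fold change of -5.25 (16 lower, 0 higher), and with ascites 2 the share was 64.7% of 17. Both lie between the bounds of 75% and 50% set for the test, so it did not decide, and the data do not tell a loss from platelets removed in handling.

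Other splits of the 12 libraries into groups of 6 were counted, 100 drawn for each comparison with the real split among them. Outside ascites 2 against ascites 1, the real split called the most genes, so a chance assignment of libraries is unlikely, as far as 100 splits can tell. For ascites 1 against medium it called 3430 genes, with at most 88 in the other splits, and for ascites 2 4657 against 28. Patients against medium gave 5562 against 318, and patients against treated cells 5645 against 277. In each, 1 of 100 was as large. Each treatment used fluid of 1 ascites donor, so chance between ascites donors is not covered. Among the 32 splits that part every donor's pair, the highest others were 35 for ascites 1 and 0 for ascites 2, with 1 of 32 as large each. With the donor as a block the real splits called 3553 and 5470 genes and the highest others 0 and 0, again 1 of 32 each. For ascites 2 against ascites 1, 3 of 100 drawn splits called at least the 3 genes of the real split, the highest other 27. That is several times the real count and points to a structure of the samples, which was not tested; that split leaves at least 1 donor's libraries together, since no other split parting all pairs called more than 5. Among the splits parting all pairs 2 of 32 called at least 3 genes, and with the donor as a block 2 of 32 called at least the 69 of the real split, the highest other 92. So among these splits chance is not excluded for this comparison in either fit.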
